A study of Drosophila melanogaster with 4 samples.

How the data were processed

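Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an antibody against histone H3 dimethylated at lysine 27 (H3K27me2, antibody Ab24684). The chromatin came from nuclei of wild-type Drosophila melanogaster larvae of instar 3 (L3), strain Oregon-R. The labels name 2 ChIP samples and 2 input samples, numbered as replicates, and assign each input to the ChIP sample of the same number. Per the labels' protocols, tissue was homogenised, fixed with formaldehyde and sonicated, and the chromatin was incubated with antibody and recovered on protein A beads. Nothing in the labels says whether the replicates came from separate populations of larvae, so the spread between them may be technical.

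Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Coordinates are those of FlyBase release 5, per the file headers. The authors deposited a list of enriched regions, called clusters here, for each ChIP replicate, and a combined list for the replicate set. The cluster caller, its thresholds, the scaling of input and the way the combined list was made are not given in the sources used here. Each deposited region has a start, an end and a score, which is the authors' own value for that region. The deposited score is above 0 in regions typed as enriched and below 0 in regions typed as depleted, and its log base is not given in the sources used here. The scale was read from the values. Distinct scores were taken over all regions, typed as enriched or depleted. Among them 398 pairs in replicate 1, 78 in replicate 2 and 246 in the combined list lay exactly 1 apart within 1e-09. By contrast, 0 pairs lay apart by the natural or decimal logarithm of a doubling. A step of exactly 1 is a doubling on a log2 scale, and scores were read as log2 values. They were used to describe, rank or filter clusters within a list and to compare the ranks and values of paired clusters between the replicates. Exact ties made up 34.8% of the clusters of replicate 1, 52.2% of those of replicate 2 and 22.9% of the combined list. The files hold no read counts, so the depth of each library is unknown and no counting interval could be given. No list was used for the input samples, and ChIP was not compared with input beyond what the deposited score already holds.

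Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Regions typed as depleted were left out of all comparisons of clusters. A single region in replicate 1 and a single region in the combined list ran past the end of their sequence and were clipped there. Shares were taken over the full length of the 13 sequences that carry clusters, 139.7 Mb in all, with assembly gaps and unmappable repeats included. The large arms are 2L, 2R, 3L, 3R and X. The Het scaffolds are the 6 placed heterochromatin sequences of release 5, and U joins sequence with no assigned place.

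The overlap of the replicates was measured in bases as the Jaccard index, shared bases over bases in either list. It was compared with 1000 circular shifts of replicate 2 within each sequence, giving a one-sided permutation p. On simulated data, lists that kept 50% or 90% of the regions were recovered at 50% and 90%, with p at or below 0.05 in 100% of 100 pairs each. Independent lists with random gaps gave such a p in 4% of 100 pairs. Independent lists on a common regular grid gave it in 93%, so the test also reads a shared regular spacing as overlap. The lists with planted sharing lay on such a grid, with their other regions at separate places. Their recovery was therefore fixed by construction, and their p does not show that the test detects sharing. All simulated regions had the same length and were scattered without large-scale clumping. The 4% with random gaps therefore need not hold for the deposited lists, whose lengths and coverage vary along the sequence. Scores were compared over reciprocally best overlapping clusters with Spearman and Pearson coefficients, across clusters, which are not independent replicates. The 95% interval of the Spearman coefficient came from the number of pairs and treats them as independent. Differences and ratios between arms have 95% intervals from 1000 bootstrap draws of 100 kb blocks. These intervals cover the placement of clusters along the sequence and not the error between samples. Coverage along the large arms was taken in bins of 200 kb. Regions typed as depleted in a list were compared with the clusters of another list against 1000 random placements of the same lengths on the same sequences, outside the enriched clusters of their own list. Both sides of a difference between arms come from the same library, so its spread is the SD of the differences within each library. With 2 ChIP samples an exact two-sided sign-flip permutation test of such differences cannot go below p = 0.5, and none was made.

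The comparisons, the rule for named regions and most alternatives were fixed before the data were examined. The rule names the 10 longest and the 10 highest-scored clusters of the combined list and the 5 longest stretches free of clusters in all 3 lists on the assembled arms. It adds genes only where an annotation of the files' own build is at hand. The reference gene table belongs to release 6, so its coordinates were not used. The planned shares of annotation classes, coverage of gene lists and counts of covered or free genes were therefore not run, and regions and chromosome arms are the named items. The alternatives were each replicate alone, the combined list, only clusters scored at or above the list median, a minimum length of 1 kb, clusters closer than 1 kb joined, other rules for sharing and pairing, and 10% left out at each arm end. A minimum of 2 kb, the large arms alone, lists without tied scores, and a contrast between replicates with XHet and YHet included were added after seeing the data.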

Results

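H3K27me2 is a mark set by the E(z) methyltransferase of Polycomb repressive complex PRC2, which also sets H3K27me3. Its distribution was measured in nuclei of wild-type L3 larvae, in 2 ChIP samples, each with its own input. The question the design poses is where along the genome the mark is enriched and how well both replicates place it. All values rest on the authors' enriched clusters in FlyBase release 5 coordinates. Read depth is unknown, and how far depth limits a list cannot be stated.

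H3K27me2 clusters covered a large part of the larval genome. They spanned 51.5 ± 4.29 Mb (SD, n = 2), or 36.8% ± 3.07 of the sequence, and 40.8% ± 4.05 of the large chromosome arms. Replicate 1 had 15589 clusters over 54.5 Mb and replicate 2 had 15021 clusters over 48.4 Mb. The combined list held 16862 clusters over 67.9 Mb, 48.6% of the sequence. The clusters had a median length of 2411 bp in replicate 1, 2252 bp in replicate 2 and 2540 bp in the combined list. The shortest measured 1226, 1301 and 1001 bp, and the first quartiles were 1809, 1675 and 1692 bp. The thresholds of the caller are not given, so how far they set these lengths is unknown. Clusters of at least 10 kb numbered 589, 435 and 1143 in these lists and held 16.1%, 12.3% and 28.1% of the covered bases. When clusters closer than 1 kb were joined, 372 domains of at least 20 kb were found in replicate 1, 276 in replicate 2 and 703 in the combined list, the longest reaching 195.9 kb.

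Enrichment within clusters was modest. The median score was 0.69 in replicate 1, 0.63 in replicate 2 and 0.50 in the combined list on a log2 scale. Scores were spread more widely in replicate 1 (SD over clusters 0.35) than in replicate 2 (0.18). Longer clusters had higher scores in each list, with Spearman coefficients across clusters of 0.681, 0.559 and 0.572.

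The replicates marked largely the same places. They shared 38.8 Mb, which was 71.1% of the bases of replicate 1 and 80% of those of replicate 2. Shifted positions gave 37.3% and 41.9%. The Jaccard index was 0.604, against a mean of 0.246 and a maximum of 0.275 over 1000 shifts (one-sided permutation p = 0.001, the smallest these shifts can give). Among the large arms it ranged from 0.580 on X to 0.664 on 2R. It was 0.33 on chromosome 4, 0.445 over the Het scaffolds and 0.343 on U, where shifts gave means of 0.0390, 0.121 and 0.0455, against 0.257 for the large arms together.

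Of the clusters of replicate 1, 76.5% touched a cluster of replicate 2, against 56.2% at shifted positions. With a reciprocal overlap of 50% required, the share was 51.5% against 16.0%. The 3663 clusters of replicate 1 with no partner were shorter and lower in score (median 1778 bp and 0.53) than the 11926 with one (2890.5 bp and 0.75). The share with a partner rose with the score, from 52.2% in the lowest of 10 equal score classes to 96.0% in class 9, and was 85.5% in class 10. Median length rose as well, from 1613 bp in class 1 to 4509 bp in class 9. A longer cluster touches the other list more often at any position. Shifted shares were not computed per class, so score and length are not told apart here. In replicate 2 the share was 74.2% in class 1, 92.5% in class 8 and 83.5% in class 10. Replicate 2 had 2204 clusters with no partner, with a median of 1648.5 bp and a score of 0.58, against 2499 bp and 0.64 for the rest. Over 10588 reciprocally best pairs the scores had a Spearman coefficient of 0.604 (95% interval 0.592 to 0.616) and a Pearson coefficient of 0.642, across clusters. The interval treats the pairs as independent, may be too narrow and does not measure the error between samples.

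The combined list took in 98.8% of the bases of replicate 1 and 94.7% of those of replicate 2. It also extended beyond them, with 10.2% of its bases in neither replicate. That share was 9.21% on the large arms, 15.9% on the Het scaffolds and 37.4% on U. The 2396 combined clusters that touched neither replicate had a median length of 1251.5 bp and a median score of 0.39.

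Coverage rose and fell largely together in both replicates along the large arms, with differences in level in places. The end Mb of each assembled arm on the centromere side was compared with the rest of the arm. On 2L, 2R, 3L, 3R and X its coverage in replicate 1 differed by -14.8, -22.6, -15.4, -15.7 and -16.0 percentage points. In replicate 2 it differed by 1.42, -0.919, 0.858, -13.1 and -7.05. Over 596 bins of 200 kb on the large arms the covered share had a Spearman coefficient of 0.863 and a Pearson coefficient of 0.874 across bins, which are not independent replicates. Bins ranged from nearly free to mostly covered. A total of 70 bins lay above 60% and 50 lay below 20% in the mean of the replicates. The highest bin was 3L 22400001 to 22600000, with 85.4% in replicate 1 and 81.2% in replicate 2. It was followed by 3R 18600001 to 18800000 with 84.7% and 75.9%. The lowest was 3R 12600001 to 12800000, with 2.29% in replicate 1 and 0% in replicate 2. The next lowest were X 15600001 to 15800000, with 5.28% and 3.47%, and the bin at the start of X, with 4.53% and 6.91%.

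**Figure D1:**
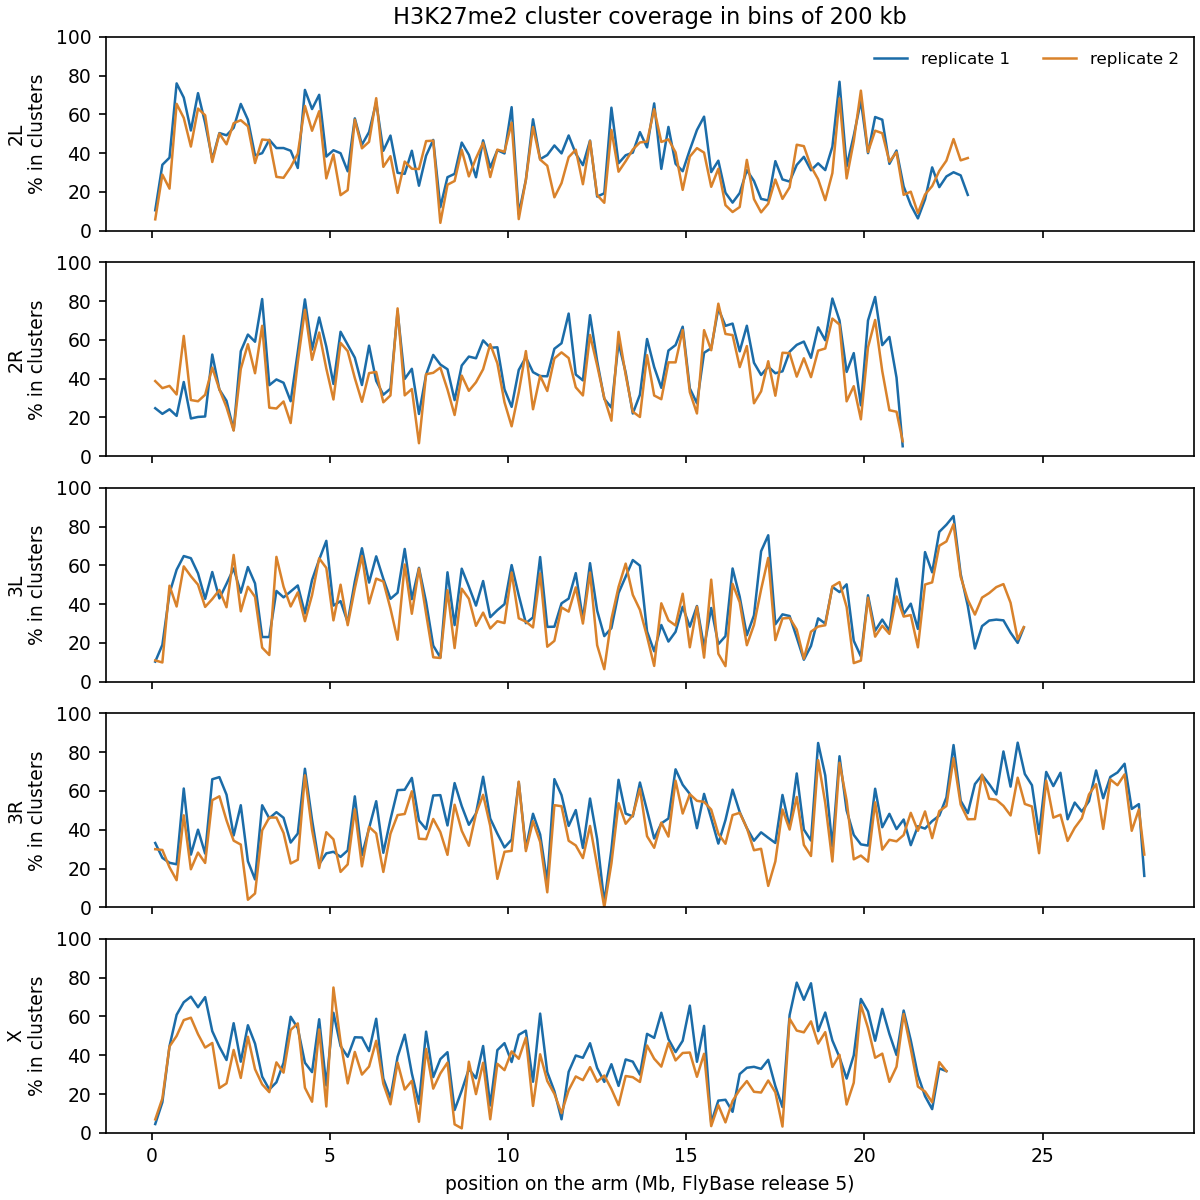
Share of bases in H3K27me2 clusters (percent, vertical axis) in bins of 200 kb along the 5 large arms (Mb, horizontal axis, FlyBase release 5), with a line for each ChIP replicate. The lines rise and fall together over most of each arm, with a Spearman coefficient of 0.863 over 596 bins.

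The longest uninterrupted cluster lay on 3L from 22295682 to 22401106 and spanned 105.4 kb with a score of 0.94. Clusters of replicate 1 covered 96.4% of it and clusters of replicate 2 covered 90.1%. The longest clusters of the single replicates lay at the same place, 53.0 kb in replicate 1 and 57.7 kb in replicate 2. The other 9 of the 10 longest combined clusters spanned at most 59.0 kb. They lay on 3R at 4268086 to 4327057 and 23235564 to 23291062, and on 2L at 4228311 to 4286431 and 922252 to 977545. On 2R they lay at 4685448 to 4742800, 19114821 to 19165701 and 1698082 to 1747802, on 3L at 10892470 to 10947059 and on X at 18598110 to 18647643. Over all 10 the share covered was 86.1% to 99.5% in replicate 1 and 71.3% to 98.6% in replicate 2. Their scores ran from 0.72 to 1.17.

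The longest stretch of the assembled arms without a cluster in any of the 3 lists lay on 3R from 12629673 to 12804390, 174.7 kb. The next lay on chromosome 4 from 24423 to 165376 (141.0 kb), on 2L from 21412464 to 21542752 (130.3 kb), on chromosome 4 from 170961 to 291601 (120.6 kb) and on 3L from 19808624 to 19926792 (118.2 kb). Stretches of at least 50 kb numbered 58, of which 18 were on X, 11 on 2R, 9 on chromosome 4, 8 on 3R, 7 on 2L and 5 on 3L. Assembly gaps and repeats inside these stretches were not excluded.

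**Figure D2:**
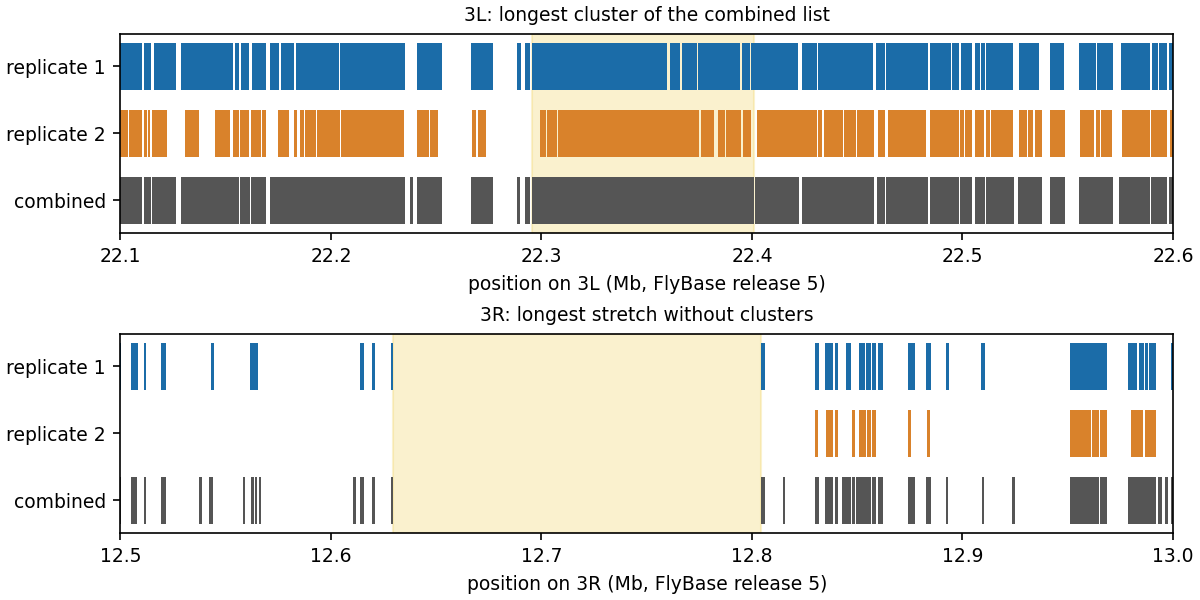
Enriched clusters (bars) of replicate 1, replicate 2 and the combined list along a pair of windows in FlyBase release 5 (Mb, horizontal axis), 22.1 to 22.6 Mb of 3L and 12.5 to 13 Mb of 3R. The shaded spans are the longest combined cluster, 105.4 kb on 3L, where both replicates carry near-continuous clusters, and the longest stretch without clusters, 174.7 kb on 3R.

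The clusters with the highest scores were short and stood apart from the long domains. The 10 highest-scored clusters of the combined list measured 1.00 to 1.87 kb with scores of 3.40 to 3.93. Of these, 7 lay on U, 1 on 2RHet (540669 to 541760), 1 on 2R (15619122 to 15620122) and 1 on 3L (23357576 to 23358592). The top one was U 7828840 to 7830709. None of the 10 was touched by a cluster of either replicate, and 9 had a score exactly tied with another cluster.

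In the mean of the replicates, each of the 4 large autosome arms and X was covered more than chromosome 4, U and each Het scaffold. Within replicate 2 a single scaffold, 3LHet (32.7%), lay slightly above X (32.5%). Coverage was 44.6% ± 4.16 on 2R, 44.6% ± 5.08 on 3R, 39.7% ± 2.74 on 3L, 37.9% ± 2.53 on 2L and 36.5% ± 5.67 on X (SD, n = 2 each). Chromosome 4, a small chromosome largely of heterochromatin, had 7.66% ± 1.86 and U had 8.58% ± 0.316. The Het scaffolds together had 21.5% ± 5.78, below the large arms together. The difference in percentage points was -26.2 in replicate 1 and -12.3 in replicate 2, a mean of -19.3 ± 9.83 (SD of the differences, n = 2). Among the scaffolds, YHet had the lowest share, 4.83% ± 1.06, and 3LHet the highest, 26.5% ± 8.88.

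The clusters found on the Het scaffolds scored higher than those on the large arms. Median scores were 0.95 against 0.67 in replicate 1, 0.84 against 0.62 in replicate 2 and 0.71 against 0.48 in the combined list. With only clusters scored at or above the list median, the difference in coverage between Het scaffolds and large arms was -8.28 percentage points in the mean. It was -15.8 in replicate 1 and -0.789 in replicate 2. This cut keeps more of the clusters on the Het scaffolds because they score higher, so the smaller difference restates those scores. The shares are of the full sequence, with gaps and repeats that reads cannot be placed in.

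**Figure D3:**
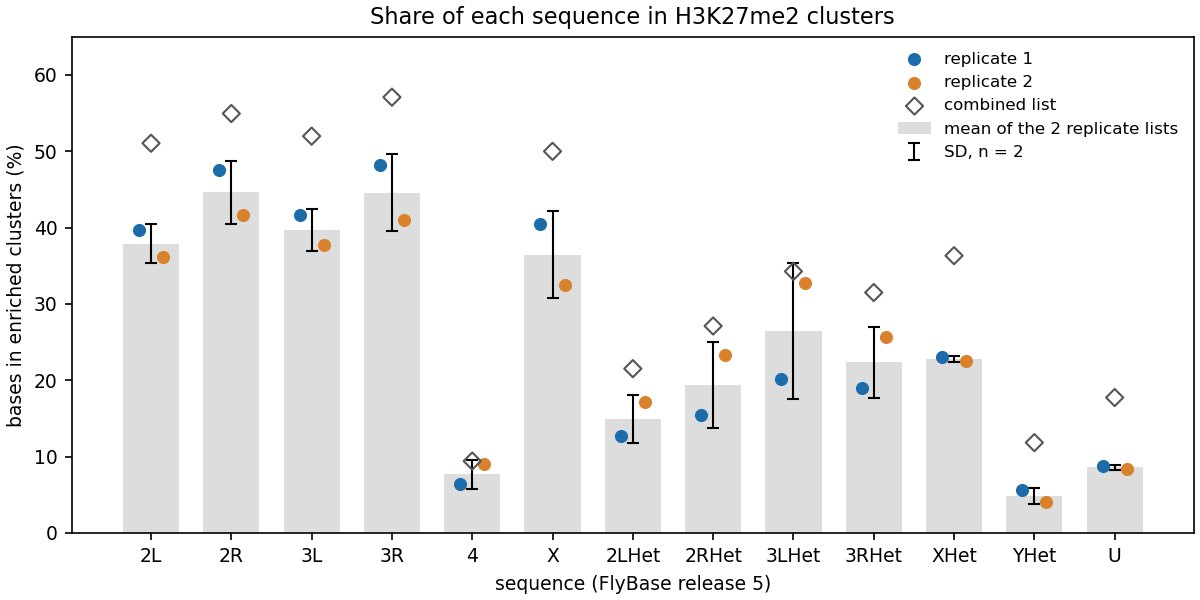
Share of each FlyBase release 5 sequence in H3K27me2 clusters (percent, vertical axis), with bars for the mean of the 2 replicate lists, error bars for the SD (n = 2), points for each replicate and diamonds for the combined list. The large arms reach means of 36.5% to 44.6%, chromosome 4 reaches 7.66%, and replicate 2 lies above replicate 1 on 4 and on the 4 autosomal Het scaffolds.

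A smaller share of X than of the mean large autosome arm lay in clusters. The autosome arms themselves ran from 37.9% on 2L to 44.6% on 2R in the mean of the replicates, against 36.5% on X. The block intervals below do not cover variation between arms. The difference between X and the mean autosome arm was -3.80 percentage points in replicate 1 (95% block interval -6.61 to -1.09), -6.68 in replicate 2 (-9.29 to -3.80) and -3.77 in the combined list (-7.04 to -0.878). In replicate 1, coverage of X (40.5%) was still above that of 2L (39.7%), and in the other lists X was the lowest of the large arms. Clusters on X scored higher, with median scores of 0.76, 0.70 and 0.53, the highest among the large arms in all 3 lists. Among clusters at or above the list median score, the difference was 2.02 percentage points in the mean of the replicates. Block intervals included 0 in each (1.55, -1.39 to 4.44, and 2.49, -0.0547 to 4.93). This cut kept 59.7% and 69.3% of the clusters on X in replicates 1 and 2. On 2R, the highest autosome arm in this respect, it kept 51.9% and 45.8%. The change restates the higher scores on X and does not locate the deficit. Over all clusters the difference within each library had a mean of -5.24 ± 2.04 (SD, n = 2). An exact two-sided permutation test by sign flips cannot go below p = 0.5 with n = 2.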

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

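The depleted regions were looked at only after their numbers and scores were known, so both tests in this part were chosen after the result was seen. The combined list types 30 regions as depleted, replicate 1 types 14 and replicate 2 types none. They stood out because they lie outside the comparisons of enriched clusters and carry a sign opposite to the antibody's target. They are short, 1382 to 1736 bp in the combined list, with scores from -0.18 to -0.00079.

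A candidate explanation is that the type only follows the sign of a continuous score near 0. In the combined list 698 enriched clusters had scores no farther above 0 than the lowest depleted score lay below it, and 53 of these lay below 0.05. No gap separated the types, and the lowest enriched score in replicate 2, which has no depleted region, was 0.15. Another candidate is depletion in the tissue. Of the 30 combined regions, 12 touched an enriched cluster of replicate 1, 6 touched its depleted regions and 12 touched neither. In replicate 2, 6 touched an enriched cluster and 24 touched none. The touched clusters of replicate 1 had a median score of 0.09, against 0.69 for all its clusters. Of the bases of the 30 regions, 38.5% lay in enriched clusters of replicate 1 and 15.3% in those of replicate 2. Means were 0.452% and 1.86% at 1000 random placements outside the combined clusters (one-sided permutation p = 0.001 each, the smallest these can give). These means are low by construction, since those clusters hold 98.8% and 94.7% of the replicates' bases. For the 14 regions of replicate 1, 22.1% of bases lay in enriched clusters of replicate 2. Random placements gave a mean of 9.05% and a 95th percentile of 21.6%. The overlap counts against depletion at most for the touched regions, and depletion stays open for the rest.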

How the results depend on the processing

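The minimum of 2 kb, the large arms alone and the lists without tied scores were chosen after seeing the data. The bases covered were 51.5 Mb in the mean of the replicates, 48.4 to 54.5 Mb with either replicate left out, 67.9 Mb in the combined list, 34.9 Mb with clusters at or above the median score and 42.3 Mb with clusters of at least 2 kb. The number of clusters was 15305 in the mean, 15021 to 15589 with either replicate left out, 7654 at or above the median score, 9939.5 after joining and 9622 at 2 kb or more. These filters and the joining change such totals by construction. The cause of the larger combined total was not tested. Between the replicates the Jaccard index ran from 0.50 to 0.621 over its alternatives, each with permutation p = 0.001. Against the combined list it was 0.786 and 0.650, which says nothing about stability, since that list takes in most bases of both. The Spearman coefficient of scores was 0.465 over all overlapping pairs and 0.654 over pairs with 50% reciprocal overlap; the cause was not tested.

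X lay below the mean autosome arm in 8 of 9 alternatives, from -6.68 to -3.80 with either replicate left out. With clusters at or above the median score it differed by 2.02 percentage points in the other direction. The block intervals of that difference include 0 in each replicate. That cut keeps more of the clusters on X, which score higher, so it is no separate check of the difference. The Het scaffolds lay below the large arms in 8 of 8 alternatives, from -26.2 to -12.3 with either replicate left out and -8.28 at or above the median score. In replicates 1 and 2 the cut at the median score kept at least 65.2% and 84.6% of the clusters of each Het scaffold. On each large arm it kept at most 59.7% and 69.3%. A filter that removes more of the arm clusters narrows this difference by construction. Of the 13 shares per sequence, 11 moved by more than the SD of the replicates in the combined list, 8 at or above the median score and 10 at 2 kb or more. The planned minimum of 1 kb removed no cluster, so it repeats the main value in both counts of alternatives and says nothing about stability. A value with either replicate left out is that of the other replicate alone, and the main value is their mean. The alternatives for annotation classes, gene lists and covered genes were not run, since no gene positions in release 5 were used. No paired analysis was possible because the shared replicate numbers join ChIP and input samples, no list was used for input, and the results come from no test between groups. Depth is unknown, so what it limits was not measured.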

Other observations

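The test of lower read depth on X, the choice of sequences in the contrast between replicates and the choice of clusters by score and length were made after the results were seen. Among the 5 highest-scored clusters of at least 10 kb on the large arms of the combined list, 4 lay on X. They were X 14082901 to 14094313 (score 1.51), X 1598491 to 1630095 (1.49), X 1416923 to 1434038 (1.47) and X 1378540 to 1407340 (1.43). The remaining one was 3L 23288559 to 23306890 (1.45). Both replicates covered each of these by at least 93.6%.

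As background from the genetic map of the fly and not from the files, the part of 3R that holds the longest stretch without clusters also holds the bithorax complex, the Hox genes of the posterior body. The part of 2L that holds the stretch from 21412464 to 21542752 also holds the tandem histone genes. Gene positions in release 5 were not used here, so how far these stretches and genes coincide was not tested. Nor was the repeat content of the histone genes, which limits where reads can be placed.

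Replicate 2 covered more of the autosomal Het scaffolds and chromosome 4 than replicate 1 and less of the large arms. On these 5 sequences it covered 2.43 Mb against 1.63 Mb, 1.49 times as much, and on the large arms 0.869 times as much. On XHet, YHet and U replicate 2 covered fewer bases than replicate 1, with ratios of 0.979, 0.731 and 0.949. Of these, only YHet lay below the ratio of the large arms. YHet held 6 clusters in replicate 1 and 9 in replicate 2, and XHet held 15 and 16. U entered neither of the ratios that follow. The ratio between the 5 sequences and the large arms, each as replicate 2 over replicate 1, was 1.72 (95% block interval 1.60 to 1.84), and 1.69 (1.59 to 1.81) with XHet and YHet included. The excess reached into the end Mb on the centromere side of the assembled arms 2L, 2R and 3L. Coverage there was 25.5%, 26.0% and 26.9% in replicate 1 and 37.5%, 40.8% and 38.6% in replicate 2. It did not do so on 3R (33.0% and 28.3%), and X had 25.2% and 25.7%.

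The values argue against short clusters as a technical explanation of this contrast. With clusters of at least 2 kb the ratio was 1.87 (1.69 to 2.07). For these lists the values also argue against the total amount called as the sole explanation. A smaller amount alone would lower coverage throughout. Replicate 2 covered less in total (48.4 against 54.5 Mb) but more on the autosomal Het scaffolds and chromosome 4 (2.43 against 1.63 Mb). A comparison at equal totals adds nothing to this. With replicate 1 reduced to its highest-scored clusters until both lists covered the same total, the ratio was 1.62 (1.5 to 1.75). Dropping clusters cannot raise the bases of replicate 1 on the autosomal Het scaffolds and chromosome 4, where replicate 2 already covered more. Equal totals also hold the large arms at nearly equal coverage. The contrast therefore could not vanish in that comparison, whatever its cause. Clusters resting on few reads stay open: without tied scores the ratio was 2.09 (1.89 to 2.31), but the files hold no reads to show that ties mark few reads, and this removed 34.8% of the clusters of replicate 1 and 52.2% of replicate 2. Differences between the input libraries or chromatin preparations were not analysed here and stay open. The ChIP samples form a single group, so no biological explanation was tested.

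A hypothesis for the smaller covered share of X is lower read depth there, which would let only stronger places pass, and it stays open. Among clusters at or above the list median score the ratio of X to the mean autosome arm was 1.05 in replicate 1 (95% block interval 0.958 to 1.15) and 1.1 in replicate 2 (0.998 to 1.21), a mean of 1.08. Below the median the ratio was 0.636 and 0.395. These values restate the higher scores on X, which had been seen already, and decide nothing between depth, not analysed here, and a real difference in weak enrichment on X. Arm ends do not account for the difference, which was -6.21 percentage points in the mean of the replicates with 10% left out at each end.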
